A study of Homo sapiens with 4 samples.

How the data were processed

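Bulk mRNA sequencing was measured in 4 libraries of T-HESC cells, 2 transfected with an AIF1 plasmid and 2 with a control plasmid, per the labels. The authors deposited a table of 50868 human Ensembl genes with raw read counts per gene and library, which are the values used here. The submitters' processing notes name TopHat and Cufflinks 2.1.1 and the builds GRCm38.p4 and hg38, without roles. GRCm38.p4 is a mouse build, although the gene identifiers are human. The counting tool, its strand setting and the annotation are not given in the sources used here. The table also holds 4 columns of FPKM values, which were not used. No row lacked a gene name.

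Column names show the group of each library but no replicate number, so columns were mapped to groups and not to individual samples. A token in the names is shared by 1 column of each group. It was taken as a possible batch, and the libraries are named by group and library set (A or B). Whether libraries deviate together by set was checked: the deviations from the group means of libraries with the same token had a correlation of 0.559 across genes, and the first principal component (64.6% of the variance) separated the sets. No libraries of a group agreed within sampling noise (chi-square per degree of freedom of 71.6 for NC and 66.0 for AIF1_OE).

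Total counts ran from 13898327 to 15142274 per library. Intervals are at 95% confidence and floors at 3 counts. The floors and the intervals of a ratio of counts cover counting error only, while the intervals of fitted log2 fold changes come from the edgeR fit and reflect the spread between libraries. Of the 50868 genes, 27628 had at least 1 count, and 15269 passed edgeR's filterByExpr. Coordinates and exon overlaps came from GENCODE release 29 (GRCh38), which held 50111 of the identifiers. Counts were normalised by TMM factors and tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation, group as the only factor) with Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are the unshrunken coefficients, with standard errors derived from the F statistic. CPM of named genes are TMM-normalised, given as mean ± SD. The within-set ratios are differences of log2 CPM with a prior count of 2. For 2 libraries per group the precision was limited: the median half-width of the 95% interval of a log2 fold change was 0.76, and 0.40 with library set as a term.

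The 27 gene lists were fixed before the data were examined, and 697 of their 698 symbols were matched. They covered decidualization, implantation and receptivity, the p38 MAPK cascade, immediate early and MAPK feedback genes, inflammatory, interferon-stimulated and antigen presentation genes, matrix proteins and proteases, actin, epithelial-mesenchymal transition, cell cycle, p53, unfolded protein response, heat shock, hypoxia, oxidative stress, cholesterol, lysosome, mitochondrially encoded, histone, and markers of stromal, epithelial, endothelial, myeloid, lymphoid and smooth muscle cells. Lists with at least 5 tested members (26 lists) were tested with camera in limma 3.58.1 (preset correlation of 0.01, two-sided), again with an estimated correlation, and with fry. The test with an estimated correlation rests on 2 residual degrees of freedom, or 1 with library set as a term, so few lists could pass it. The rule for named genes was also fixed beforehand. It takes AIF1, up to 10 genes per direction past the threshold, or the 5 with the smallest p where fewer than 5 pass, up to 4 members of each list past the threshold or the 2 with the highest expression, and 16 fixed genes.

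Alternatives were RLE factors, DESeq2 1.42.0, no filter (at least 1 count over all libraries), a stricter filter (1 CPM in at least 2 libraries and a mean of 10 counts), each library left out in turn, and an absolute log2 fold change of at least 1. Library set as a term, limma-voom, and combinations with the set term were added after seeing the data. The tests were tried on simulated counts before use (5 runs, 200 genes changed, median of 14977 genes tested for AIF1_OE against NC). The fit on group alone recovered 0% of 1.5-, 2- and 4-fold changes. With library set as a term 13.5% of 1.5-fold, 60.5% of 2-fold and 93.7% of 4-fold changes were recovered, and 3.57% of calls were false. The simulated genes varied only by a smooth trend on expression, without large deviations of single libraries. These shares therefore need not hold for the real libraries. Figures were drawn with matplotlib 3.10.9.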

Results

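The measured cells were T-HESC, a human endometrial stromal cell line immortalised with telomerase. They were transfected with a plasmid for AIF1, which encodes allograft inflammatory factor 1, an actin- and calcium-binding protein best known from macrophages (group AIF1_OE, 2 libraries), or with a control plasmid (group NC, 2 libraries). RNA was collected 3 days after transfection and sequenced as mRNA. The comparison asks which transcripts differ between these stromal cells with the AIF1 plasmid and with the control plasmid. The study is concerned with p38 MAPK phosphorylation and endometrial receptivity. Phosphorylation itself was not measured in these data. Total gene counts were 15090784 and 13898327 in the AIF1_OE libraries and 14987946 and 15142274 in the NC libraries, and 15269 genes had enough counts to be tested. Each group has 1 library in each of 2 sets that share a token in their column names, called library set A and library set B here. The meaning of the token is not stated. Nothing states whether the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

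AIF1 itself (ENSG00000204472, chromosome 6, 31615184 to 31617021 on the plus strand of GRCh38, 5 annotated transcripts) was counted 5 times in the AIF1_OE library of set A and 2 times in that of set B. It was counted 0 times in both NC libraries. The 7 counts among 28989111 correspond to 0.241 CPM. A count of 0 among the 30130220 NC counts allows up to 0.0996 CPM (3 counts over the group). With the 7 counts taken as exact, AIF1 was at least 2.43-fold higher in AIF1_OE than in NC, computed against that limit. With their counting error included, the lower limit of the 95% interval of the ratio was 1.498-fold (exact conditional test, two-sided p = 0.00682, which compares these libraries and covers counting error only). That limit was 1.83-fold without the AIF1_OE library of set B, but 0.407 without that of set A, 0.753 without the NC library of set A and 0.745 without the NC library of set B, so the difference was not detectable when any of these 3 libraries was left out. AIF1 did not pass the filter of the planned test across genes. Fitted without the filter, it did not pass either (edgeR, adjusted p = 0.99999, or 0.990 with library set as a term). The unadjusted p of those edgeR fits was 0.0534, or 0.110 with library set as a term. PRRC2A, which lies beside AIF1, had between 4358 and 5742 counts in every library. The neighbours LST1 and LTB had 1 and 3 and 2 and 3 counts in AIF1_OE and 0 in both NC libraries. NCR3, another neighbour, had 0 in both AIF1_OE libraries and 2 and 0 in NC.

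The well-counted genes among those with the smallest p in the planned test separated the AIF1_OE from the NC libraries in both library sets. TIMP2, an inhibitor of matrix metalloproteinases, stood at 1483 ± 29.8 CPM (counts scaled by library size) in AIF1_OE and 332 ± 73.5 in NC (SD, n = 2), a 4.46-fold difference (log2 2.16 ± 0.27 SE). MAFG, a small MAF transcription factor, stood at 155 ± 6.11 against 45.4 ± 1.59 CPM (log2 1.77 ± 0.18). STX6, a syntaxin of endosomal and Golgi trafficking, differed by 1.71 ± 0.21. In the other direction lay RASSF8 (log2 -2.39 ± 0.44), FAM45A (-2.09 ± 0.22), the metalloreductase gene STEAP2 (-1.89 ± 0.21), MAFF, another small MAF factor (-1.59 ± 0.20), and CAB39, a partner of the kinase LKB1 (-1.42 ± 0.24). Each of these 8 genes had the same direction in both sets, which their choice by the smallest p largely builds in. Of all well-counted genes over 2-fold in both sets, 15 went the same way and 7 opposite ways.

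None of these genes passed the planned test. With edgeR's quasi-likelihood fit on the group alone, 0 genes were higher and 0 lower at an adjusted p of 0.05, and the smallest adjusted p was 0.99998. An unadjusted p under 0.05 was reached by 139 genes, fewer than the 763 that chance alone would give. On the same libraries DESeq2 gave 13 higher and 6 lower genes, and limma-voom gave 0. The edgeR fit on group alone had a biological coefficient of variation of 0.294, and on simulated counts with the same library structure it recovered 0% of 4-fold changes among 14977 genes tested, so its count of 0 does not bound changes of that size.

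With library set as a term, an analysis chosen after seeing the data, 3 genes rose and 6 fell in AIF1_OE at an adjusted p of 0.05 in edgeR. MAFG (adjusted p = 0.0360) and TIMP2 (adjusted p = 0.0483) rose. RASSF8 fell (adjusted p = 0.0163), as did FAM45A, STEAP2, MAFF and CAB39 (each adjusted p = 0.0483). The set A and set B log2 ratios were 1.97 and 2.38 for TIMP2, 1.69 and 1.85 for MAFG, and -2.26 and -2.45 for RASSF8. STX6 missed the threshold (adjusted p = 0.0552). All 9 genes were also among the 42 that DESeq2 called with the same term, and among the 19 it called without it, whereas limma-voom with the term called 4 of them (RASSF8, MAFG, TIMP2 and CAB39). With the stricter filter RASSF8 alone stayed past the threshold (adjusted p = 0.0279), and 8 of the 9 calls were lost, with an adjusted p of 0.0544 for MAFG and 0.0685 for TIMP2. MAFG, RASSF8 and TIMP2 overlap exons of other genes, which held at most 357, 197 and 79 counts in a library. FAM45A has a near-identical copy, FAM45BP, counted 549 and 478 times in AIF1_OE and 500 and 541 times in NC, so its counts are less certain.

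The other genes past the threshold with library set as a term were transcripts that overlap better-counted genes. XXbac-BPG300A18.13, a 3' overlapping non-coding RNA within PBX2, had 174 and 56 counts in AIF1_OE against 1 and 0 in NC, a ratio of 239 with a counting interval of 42.5 to 9483. The read-through transcript ATP6V1G2-DDX39B had 3 and 1 counts in AIF1_OE against 359 and 27 in NC. Summed with the genes whose exons it overlaps, ATP6V1G2-DDX39B differed by -0.03 in set A and 0.01 in set B on the log2 scale. The same sum for XXbac-BPG300A18.13 with PBX2 gave -0.36 and 0.02. The overlapping genes held most of these sums, of which the transcripts themselves made up at most 16.3% and 25.1%. The gene ENSG00000268575 (log2 1.78 ± 0.25), which shares exons with CDK11A, did not pass (adjusted p = 0.127).

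**Figure D1:**
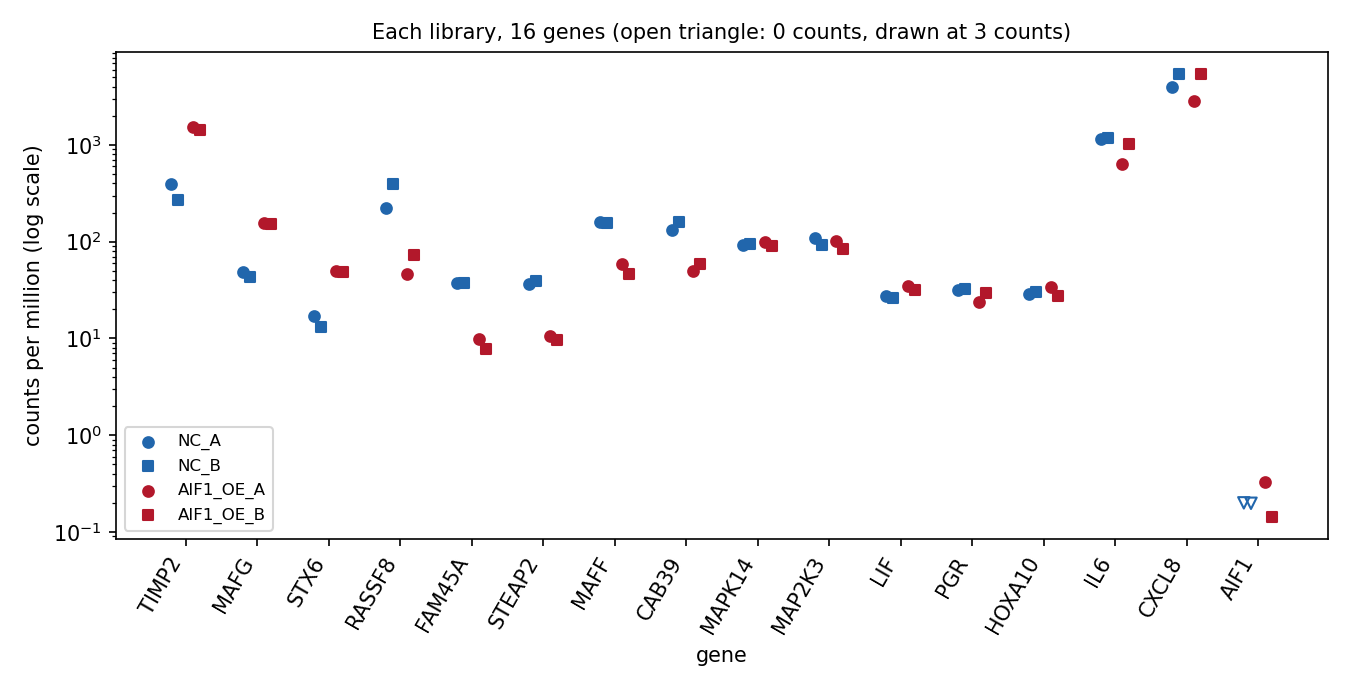
CPM of the library total (log axis) for 16 genes, with NC libraries in blue, AIF1_OE libraries in red, circles for set A and squares for set B; an open triangle marks 0 counts, drawn at the level of 3 counts. The 2 AIF1_OE points lie above both NC points for TIMP2, MAFG and STX6 and below them for RASSF8, FAM45A, STEAP2, MAFF and CAB39, while AIF1 lies at 5 and 2 counts.

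Most of the well-counted genes were close to equal between the groups. Among the 7831 genes with a mean of at least 300 counts (51.3% of those tested), 7296 (93.2%) differed by less than 1.5-fold in both library sets. Among the 7438 tested genes with fewer counts, 4896 (65.8%) did. The central 90% of log2 ratios of the well-counted genes ran from -0.34 to 0.37 in set A and from -0.34 to 0.34 in set B. Across all tested genes, which are not independent replicates, the ratios of the sets had a correlation of -0.02.

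**Figure D2:**
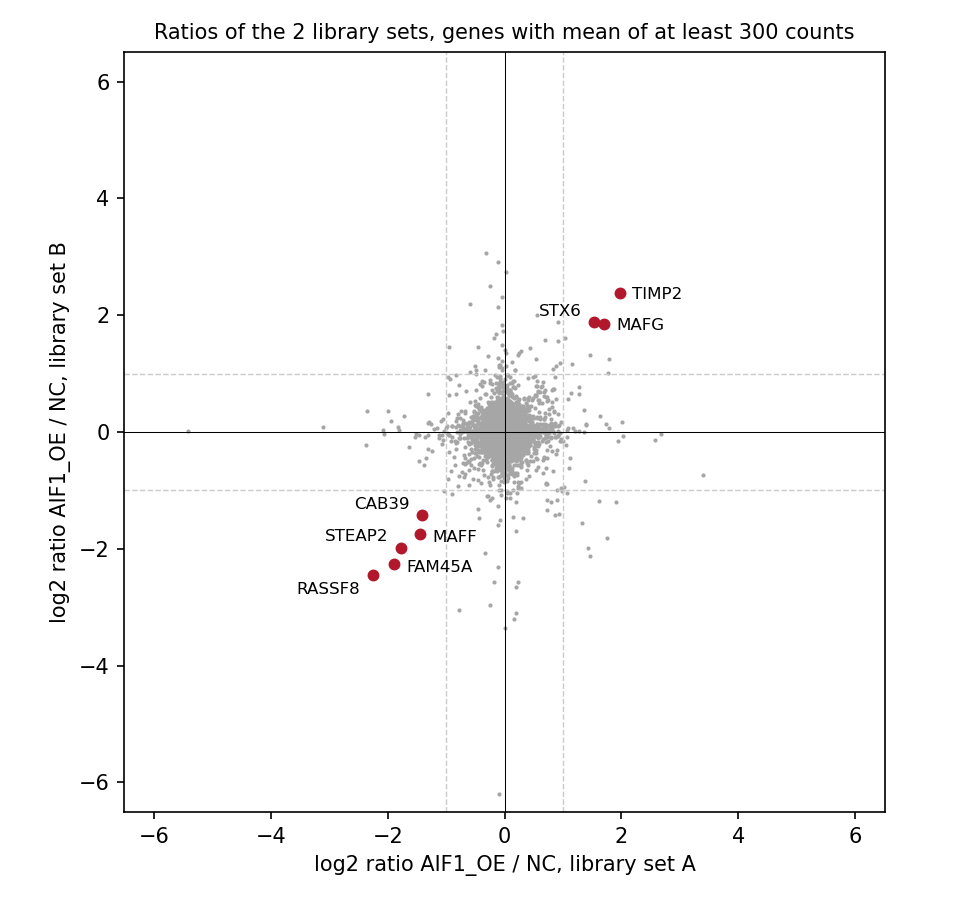
Each point is a gene with a mean of at least 300 counts (7831 genes), placed by its log2 ratio of AIF1_OE to NC in library set A (horizontal) and in library set B (vertical); dashed lines mark a 2-fold difference. Genes named by the smallest p in the planned test are in red, with TIMP2 at 1.97 and 2.38 and RASSF8 at -2.26 and -2.45.

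Genes of the p38 MAPK cascade did not differ detectably, in a planned fit that recovered 0% of simulated 4-fold changes. The same limit holds for single members of the other lists below when adjusted over all genes. It does not describe the adjustment over a list alone or the tests of whole lists. Each ± of a log2 difference in the planned fit also holds the difference between the library sets. Of 33 members tested 0 passed, over all genes and adjusted over the list alone, and their median log2 difference was 0.00. With library set as a term 0 passed as well, in either adjustment. MAPK14, which encodes p38 alpha, stood at 95.6 ± 2.11 CPM in AIF1_OE and 93.2 ± 5.65 in NC (log2 0.04 ± 0.18, 95% interval -0.42 to 0.49). MAPK11, the p38 beta gene, differed by 0.46 ± 0.37, and the upstream kinase genes MAP2K3 and MAP2K6 by -0.12 ± 0.19 and -0.68 ± 0.54. The substrate gene HSPB1 differed by -0.01 ± 0.39 and the phosphatase gene DUSP1 by -0.39 ± 0.58. In the fit with library set as a term MAPK14 differed by 0.04 ± 0.10 and MAPK11 by 0.50 ± 0.17. In that fit MAP2K3 differed by -0.12 ± 0.09, MAP2K6 by -0.65 ± 0.42, HSPB1 by 0.02 ± 0.09 and DUSP1 by -0.32 ± 0.12. Among 33 immediate early and MAPK feedback genes 0 passed, with PHLDA1 at 0.72 ± 0.35 (0.22 in set A and 1.31 in set B) and IER3 at -0.07 ± 0.30. In the fit with library set as a term, adjusted over the list alone, 1 passed. It was IER2 (1.79 in set A and 1.26 in set B), chosen after its values were seen.

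Genes of decidualization and receptivity gave 0 of 19 and 0 of 22 members past the threshold, with medians of 0.01 and -0.01. LIF, a cytokine required for implantation in mice, stood at 33.2 ± 0.872 against 27.1 ± 0.438 CPM (log2 0.30 ± 0.19). The progesterone receptor gene PGR differed by -0.26 ± 0.23, HOXA10 by 0.06 ± 0.21, HOXA11 by 0.09 ± 0.18, FOXO1 by 0.19 ± 0.42 and the integrin gene ITGB3 by -0.12 ± 0.43. WNT5A differed by -0.03 ± 0.56 and IL6ST, the receptor subunit shared by LIF and IL6, by 0.07 ± 0.37. With library set as a term the values were -0.01 ± 0.08 for WNT5A and 0.07 ± 0.08 for IL6ST. PRL and IGFBP1, the classical secreted products of decidual cells, were too low to test, with 0, 0, 2 and 0 counts of PRL and 0, 0, 0 and 8 counts of IGFBP1 in the AIF1_OE libraries of sets A and B and the NC libraries of sets A and B.

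Inflammatory and interferon genes also gave no member past the threshold. The 30 inflammatory genes tested had a median log2 difference of -0.08, with IL6 at -0.47 ± 0.33 and CXCL8 at -0.15 ± 0.45. The set A and set B ratios were -0.84 and -0.20 for IL6 and -0.46 and 0.03 for CXCL8. The 41 interferon-stimulated genes had a median of -0.05, with ISG15 at -0.16 ± 0.69, and the 16 antigen presentation genes had a median of 0.01, with HLA-B at 0.07 ± 0.47. ISG15 differed by -0.16 ± 0.08 and HLA-B by 0.05 ± 0.09 with library set as a term. In that fit IL6 differed by -0.52 ± 0.18 and CXCL8 by -0.22 ± 0.14 (edgeR, adjusted p = 0.997 for each).

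Among 27 matrix proteases and inhibitors, TIMP2 passed when adjusted over the list alone and 0 members passed over all genes. MMP1 differed by 0.00 ± 0.53 and MMP2 by 0.06 ± 0.26. The 30 collagen and matrix genes gave 0 past the threshold, with FN1 at 0.08 ± 0.31 and THBS1 at -0.09 ± 0.54. The actin cytoskeleton list (32 tested, median -0.06), the epithelial-mesenchymal transition list (19, median -0.01, VIM at -0.18 ± 0.42) and the stromal fibroblast markers (16, median 0.04, COL1A1 at 0.08 ± 0.64) likewise had 0 members past the threshold. VIM differed by -0.13 ± 0.13 and COL1A1 by 0.11 ± 0.09 with library set as a term.

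Growth, stress and metabolic lists followed the same pattern, with 0 members past the threshold in each. Their medians were 0.02 for 36 cell cycle genes, 0.06 for 28 p53 targets and apoptosis genes, -0.00 for 34 unfolded protein response genes, -0.01 for 18 heat shock genes, -0.02 for 27 hypoxia and glycolysis genes, -0.04 for 24 oxidative stress genes, -0.02 for 23 cholesterol synthesis genes, 0.03 for 28 lysosome genes, 0.09 for 13 mitochondrially encoded transcripts and 0.04 for 10 histone genes. TOP2A differed by -0.00 ± 0.43, CDKN1A by 0.07 ± 0.26, HSPA8 by -0.02 ± 0.31, GAPDH by 0.07 ± 0.24 and the autophagy receptor gene SQSTM1 by 0.68 ± 0.29. With library set as a term SQSTM1 differed by 0.71 ± 0.13 and did not pass over all genes (edgeR, adjusted p = 0.548). In that fit TOP2A differed by -0.03 ± 0.09, CDKN1A by 0.06 ± 0.08, HSPA8 by -0.03 ± 0.08 and GAPDH by 0.08 ± 0.08. With library set as a term and adjusted over the list alone, TIMP2, the immediate early gene IER2 (1.79 in set A and 1.26 in set B) and the cholesterol synthesis gene DHCR24 passed. The difference of DHCR24 in the planned fit was 0.69 ± 0.25. IER2 and DHCR24 were chosen after their values were seen.

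Markers of other cell types gave 0 genes past the threshold. The medians were 0.23 for 9 endometrial epithelium markers, 0.02 for 9 endothelium markers, -0.00 for 6 macrophage and myeloid markers and -0.36 for 12 smooth muscle and pericyte markers. ACTA2 differed by -0.44 ± 0.74 and KRT18 by 0.07 ± 0.23. With library set as a term ACTA2 differed by -0.37 ± 0.10 and KRT18 by 0.05 ± 0.18 (edgeR, adjusted p = 0.997 for each). A single lymphocyte marker, CD7, could be tested (0.94 ± 0.68, at most 28 counts). By limma camera with a preset correlation, 0 of 26 lists passed in the planned design, and the lowest adjusted p was 0.118 for the epithelium markers. For 8 lists, the p38 cascade, decidualization, receptivity, cell cycle, unfolded protein response, cholesterol, stromal and myeloid lists, the median, the mean and the test differed in sign. With library set as a term the epithelium markers passed (adjusted p = 0.0482), and the call was lost with no filter (adjusted p = 0.607) and with the stricter filter (adjusted p = 0.246). The list also did not pass with an estimated correlation (adjusted p = 0.974), but with 1 residual degree of freedom that test could hardly pass a list. The member of that list with the smallest p was CLDN4, at 13 and 12 counts in AIF1_OE against 1 and 2 in NC. With voom values in place of log2 CPM and the same term, the smooth muscle markers passed as lower and the mitochondrially encoded transcripts as higher (each adjusted p = 0.0111), beside the epithelium markers (adjusted p = 0.0332). On log2 CPM the first 2 did not pass (adjusted p = 0.117 and 0.299, and 0.974 for each with an estimated correlation).

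**Figure D3:**
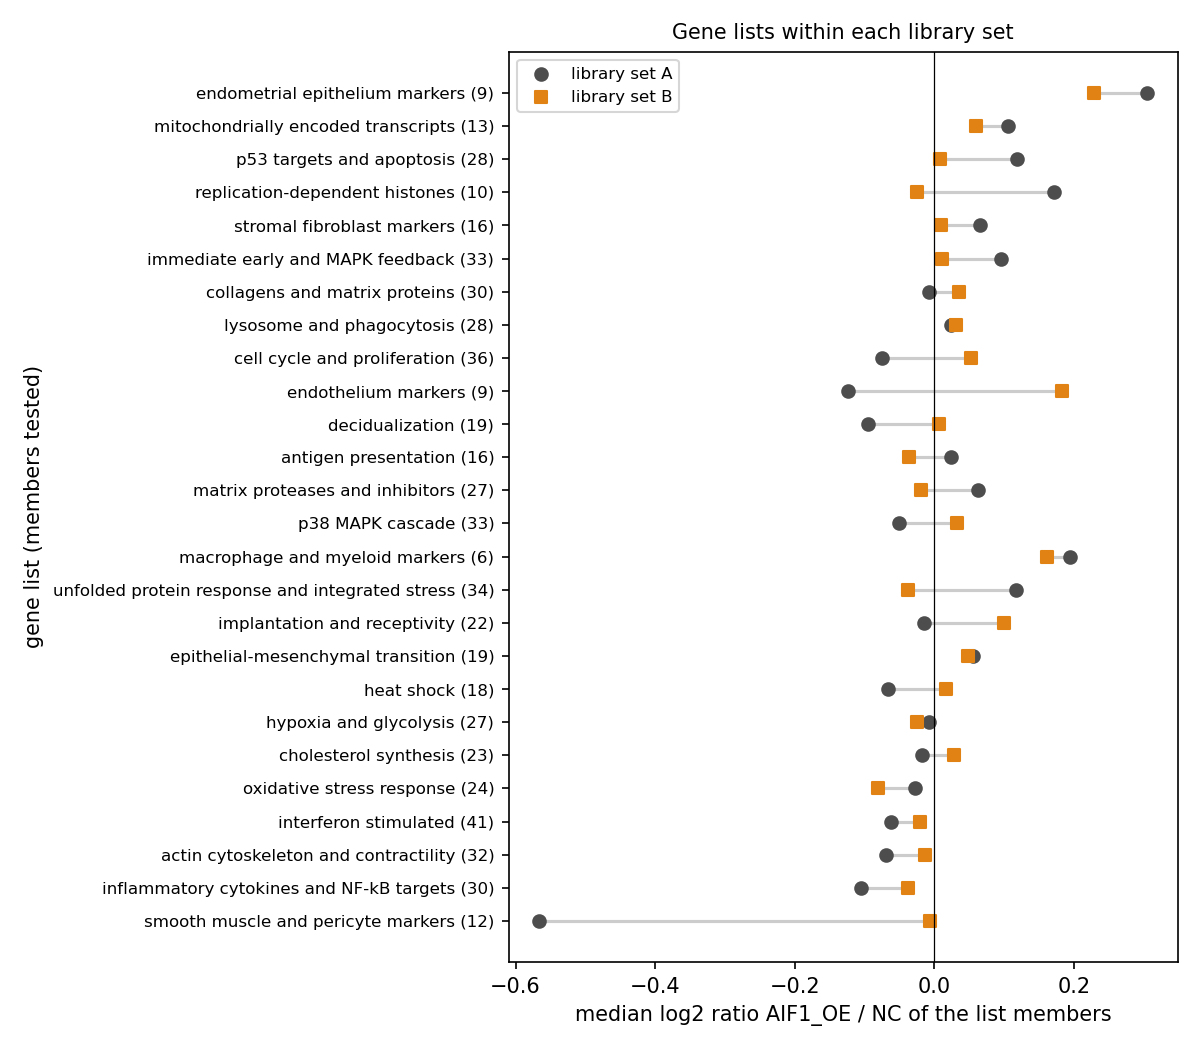
Median log2 ratio of AIF1_OE to NC over the tested members of each of 26 gene lists (number tested in brackets), in library set A (circles) and library set B (squares). For 24 lists both medians lie within 0.2 of 0; the epithelium markers lie at 0.31 and 0.23, and the smooth muscle markers at -0.57 and -0.01.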

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

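The fits with library set as a term and limma-voom were chosen after seeing the data, and the cause of each difference was not tested except where named. Against 0 genes higher and 0 lower in the planned edgeR fit, DESeq2 gave 13 higher and 6 lower, and no filter gave 7 higher and 3 lower; RLE factors, the stricter filter, the added fold threshold and limma-voom gave 0 in both directions. With each library left out in turn, 0 to 16 genes were higher and 1 to 9 lower, with the lone library of a group assumed to vary like the other group. The numbers of lists that were higher and lower then ran from 1 to 4 and from 1 to 3, against 0 and 0. The interferon list passed in every such fit, higher in AIF1_OE when a library of AIF1_OE in set B or of NC in set A was left out and lower otherwise, which follows from the unequal share of the sets in each fit. Against the limit of 3 NC counts, and with the AIF1_OE counts taken as exact, the log2 difference of AIF1 ran from 0.27 to 1.73 with a library left out, and there was no value without the AIF1_OE library of set A. With no filter AIF1 was fitted and did not pass (adjusted p = 0.99999), and RLE factors, DESeq2 and the stricter filter gave no value for it.

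No analysis paired by replicate number was possible because the columns carry none; the replicate block used the library set. It gave 3 higher and 6 lower genes, also with RLE factors. With the block, DESeq2 gave 30 higher and 12 lower, limma-voom 2 and 2, no filter 59 and 32, and the stricter filter 0 higher and 1 lower (RASSF8). Lists with the block were 1 higher (camera), 1 with RLE factors, and 2 higher (epithelium markers and mitochondrially encoded transcripts) and 1 lower (smooth muscle markers) with voom values; no filter, the stricter filter, an estimated correlation and fry gave 0.

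Without 1 library the log2 difference of named genes ran from -0.76 to 0.27 for CXCL8, -1.03 to 0.50 for DUSP1, -0.16 to 0.48 for FOXO1, -0.058 to 0.17 for HOXA10, -0.67 to 0.35 for ITGB3, -0.029 to 0.10 for MAPK14 and -0.59 to 0.38 for VIM, none of them past the threshold. These ranges also hold the difference between the library sets, whose shares are unequal once a library is left out. Within the sets DUSP1 (-0.50 in A and -0.14 in B) and ITGB3 (-0.20 and -0.07) kept their direction. CXCL8, FOXO1, HOXA10, MAPK14 and VIM differed in direction between the sets. The pseudocount setting did not apply to counts.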

Other observations

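The comparisons of the library sets, and the tests of AIF1, of overlapping genes and of jumps, were chosen after the values were seen, as were the tests of library size and counting error; the tests of abundant genes and GC content were fixed before theirs. Between the library sets, with group kept in the model, 1470 genes were higher and 1495 lower in set B at an adjusted p of 0.05 (edgeR). The p-values and ± values of this comparison rest on how alike the ratio of set B to set A was in NC and AIF1_OE. They do not measure how sets vary, since there were only 2 sets. Interferon-stimulated genes stood out: 35 of 41 fell and 1 rose in set B (camera adjusted p = 1.5e-12, or 0.689 with an estimated correlation). IFI6 fell by 2.16 ± 0.22 on the log2 scale, ISG15 fell by 1.51 ± 0.08 and MX1 fell by 1.10 ± 0.08. The ratio of set B to set A was -1.51 in NC and -1.50 in AIF1_OE for ISG15, -1.13 and -1.07 for MX1, but -2.53 and -1.79 for IFI6. IRF1 rose by 0.57. Of 16 antigen presentation genes 10 fell, with HLA-B at -0.88 ± 0.09 (adjusted p = 0.689 with an estimated correlation).

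In the same direction of comparison, all 13 mitochondrially encoded transcripts rose (MT-CO1 by 1.37 ± 0.08), and they took 3.75% and 3.57% of counts in the set B libraries against 1.76% and 1.66% in set A. Of 36 cell cycle genes 15 rose and 0 fell, with TOP2A at 0.87 ± 0.09. Collagen and matrix genes gave 15 higher and 3 lower of 30 (COL1A1 1.33 ± 0.09), and 13 of 30 inflammatory genes rose and 2 fell. TERT, the gene used to immortalise the line, stood at 849 CPM in set A and 3893 in set B, in both groups alike (2.13 in NC and 2.27 in AIF1_OE on the log2 scale). With an estimated correlation none of these lists passed, with an adjusted p of at least 0.689. That test had 1 residual degree of freedom here, so its failure says little about whether the lists moved.

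For the library set difference, 2965 genes in all, unequal library size was argued against, since the NC libraries, with totals 1.03% apart, differed between the sets by a median absolute log2 ratio of 0.343 (bootstrap interval over genes 0.335 to 0.350), and the set B libraries, with totals 8.95% apart, by 0.156 (0.152 to 0.160). A few abundant genes were argued against too, since 2934 stayed without 39 of the mitochondrial and most counted genes. Correcting each library for GC content and transcript length left 1447, and the median absolute log2 difference of these 2965 genes went from 0.71 to 0.56 with a similar median standard error (0.111 before and 0.108 after), so that trend may account for part of the difference. Of the 35 interferon genes lower before the correction 32 were also lower after it, and all 13 mitochondrial transcripts were higher before and after it. A batch of culture and a batch of library preparation cannot be told apart here, since nothing states what the sets are, and no biological explanation was tested.

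For AIF1, at 7 counts in the AIF1_OE libraries, a loss of counts that reached the nearby genes PRRC2A and BAG6 was argued against, since their lowest count in a library was 2529. A narrower loss, over AIF1 and neighbours with few counts in every library, was not tested. A swap of labels between the groups stays open, since the difference between libraries did not pass (edgeR without a filter, unadjusted p = 0.0534) and the plasmid transcript need not be counted under the gene. A plasmid transcript that the counting did not assign to the gene, or cells that had lost the plasmid, may leave the same 0.241 CPM, and these cannot be told apart without reads. LST1 and LTB, which lie close to AIF1, had 1 and 3 and 2 and 3 counts in AIF1_OE and 0 in NC, at or near the counting limit, while NCR3, another neighbour, had 0 in AIF1_OE and 2 and 0 in NC.

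For the 9 genes called with library set as a term, counts split between overlapping genes stay open for XXbac-BPG300A18.13 and ATP6V1G2-DDX39B: their summed counts differed by at most 0.36 on the log2 scale, but by at most 0.26 also if the overlapping genes had not moved, so the sums decide nothing. Such a split was argued against for MAFG, RASSF8 and TIMP2, whose sums differed by at least 1.32 and whose overlapping genes held at most 357 counts in a library, while STEAP2, CAB39, FAM45A and MAFF have no exon-overlapping gene with counts in the annotation used. Counting error alone was argued against, since each of the 9 differed the same way in both sets with an exact two-sided p of at most 3.67e-07 (threshold 3.27e-06 after Bonferroni adjustment over all tested genes), which shows only that these libraries differed. Jumps of single libraries that fall on genes independently in each set were argued against, since the 88 genes over 2-fold in set A and the 105 in set B would then give 0.59 genes in each relative direction, against 15 the same way and 7 opposite ways. Jumps in genes prone to them, agreeing in direction by chance, stay open (15 against 7, exact binomial, two-sided p = 0.134), and an effect of the AIF1 plasmid on the other 7 genes remains a hypothesis.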
